A study of Rattus norvegicus with 2 samples.

How the data were processed

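The series holds 2 one-colour arrays, 1 of rat dental papilla cells in odontogenic induction medium and 1 of the same cells with 10 nM melatonin added, both after 3 days. Both sample titles end in a count that no label explains, so whether each array read 1 culture or a pool is not given in the sources used here, and each was taken as 1 sample. Per the labels' protocols, total RNA was labelled with Cy3. The scanner files give brightness values, and per the file headers these spot intensity values were extracted by Agilent Feature Extraction 11.0.1.1 (also named in the submitters' processing notes) for array design 028282, whose annotation names build rn4. The processed intensity used here was background-subtracted and spatially detrended by that software, per the file headers, and was not normalized between arrays. The deposited files also carry flags per spot (well above background, saturated, outlier, control), and these were used as given. The series' table of processed values was deposited on a scale that matched log2 of the scanner signal (Pearson correlation across probes 0.9997 for the OS array and 0.999 for the melatonin array). Both columns of that table had a median of 5.10 and nearly one shared distribution, with a largest difference between sorted values of 0.049. How the authors normalized those log2 values is not given in the sources used here.

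Each array held 44254 spots, 42877 of them outside the controls, for 30367 probes, of which 1390 were spotted 10 times and 28977 once. Outlier spots flagged on either array (937 outside the controls) were left out, which removed 8 probes. The processed signal was put on the log2 scale, each array's 75th percentile over its probes was subtracted, spots of a probe were averaged, and probes well above background on both arrays were averaged per gene. The scanner files held accessions and no gene names. Symbols came from matching unversioned RefSeq accessions to a table of assembly GRCr8, which was used for names alone; since the builds differ, no coordinates are given. Of 30359 probes 17992 (59.3%) received a symbol, for 15158 symbols, and 4983 measured features without a symbol were counted and not named. Of these, 89 were at least 2-fold higher and 161 lower.

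With 1 array per group no test between the groups was run and no p-value is given. A ratio is the melatonin array over the OS array, a gene counted as higher or lower at 2-fold, and the number of arrays limits the precision. The spread between spots of probes printed 10 times describes the spot-level error alone, not that between cultures. For 36 gene lists fixed before the data were examined, the median log2 ratio was set against 10000 random lists of the same size matched on 10 bins of mean expression, and a list stood apart below the 2.5th or above the 97.5th percentile. Lists with fewer than 5 measured genes got no percentile. The percentiles describe these 2 arrays. For a gene well above background on 1 array only, the bound is its signal there over the higher of its own signal on the other array and the lowest signal of any probe well above background there, after scaling.

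Genes were named by a rule set in advance. It took the 12 largest higher and 12 largest lower ratios among measured genes with a mean signal at or above the lower quartile. The probes of such a gene that were well above background on both arrays had to move the same way, and its other probes were not checked. The rule also took all measured members of the odontoblast and melatonin lists. From each other list it took up to 4 members past 2-fold, or else its 2 largest. Among genes on 1 array only it took the 4 largest bounds in each direction. The values of 2 list members that the rule would name are not reported here. Other genes that are named were chosen after their values were seen, and the text says so where they appear.

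Alternatives set in advance were quantile normalization, equal medians of detected probes, loess correction on mean signal, no filter on dim probes, a filter at the lower quartile of mean signal, the brightest probe of each gene, flagged spots kept, the authors' processed values, other fold thresholds and another detection flag. Normexp with an offset of 50 was planned on the mean spot signal, and the median spot signal was chosen in its place after seeing the data. The gene and list steps were tested on simulated arrays made from the real OS array with 9204 genes. Of the genes changed by 3, 4 and 6-fold 100% were called at 2-fold, of those changed by 1.5-fold 2%, and 0 of 8604 unchanged genes. Of 20 shifted lists 100% were found, and 1 of 20 unshifted lists was called. The simulated noise was normal with 1 SD for all spots, below the SD of 0.307 across real genes read by 1 spot. Detection flags were copied from the OS array. The lists were shifted by 1.23-fold, more than the median of any list that stood apart. These shares are therefore not error rates of the real arrays. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and R 4.3.3 with limma 3.58.1; figures used matplotlib 3.10.9.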

Results

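Dental papilla cells are the mesenchymal cells of the developing tooth from which odontoblasts, the cells that lay down dentin, arise. The series asked how melatonin, the pineal hormone, alters gene expression while rat dental papilla cells differentiate toward odontoblasts. Primary cells from postnatal day 1 to 3 were held for 3 days in an odontogenic induction medium (OS) with β-glycerophosphate at 10 mM, ascorbic acid at 0.2 mM, dexamethasone at 0.1 mM and 8% serum, without melatonin or with 10 nM melatonin. Total RNA of each condition was hybridised to 1 one-colour Agilent rat expression array, so there was 1 array per group, 2 arrays in all, both on the same slide. No replicate error between cultures exists for any value here, no test between the conditions was possible, and each ratio compares these 2 arrays. On the OS array 16773 of 30367 probes (55.2%) were well above background, and on the melatonin array 14700 (48.4%). The 75th percentile of the processed signal was 428 and 329, and no spot was saturated on either array.

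Of 8226 genes with a symbol that were well above background on both arrays, 21 were at least 2-fold higher with melatonin and 58 at least 2-fold lower. Without the filter on dim probes 1859 genes were higher and 229 lower, but these counts include probes at background, where the negative control probe itself had a log2 ratio of 0.87 after scaling, so they do not bear on the direction among measured genes. Among named genes with a mean signal at or above the lower quartile, Igfbp7, a secreted protein that binds insulin-like growth factors, stood highest at 4.15-fold, and Otor, a secreted protein of cartilage and inner ear, lowest at 4.39-fold lower. The Otor value rests on 1 probe, since its other probe was not well above background on either array. The 2 profiles were otherwise close: 95.3% of these genes lay within 1.5-fold, the median log2 ratio of melatonin over OS was 0.039, and the SD across genes was 0.286. The log2 signals of the 2 arrays had a Pearson correlation of 0.993 across genes, which are not independent replicates. A 3-fold threshold left 3 higher and 10 lower genes, and normexp background correction gave 9 and 35.

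Among the other higher genes, Mrpl21, a protein of the mitochondrial ribosome, was 3.75-fold higher, Yme1l1, a protease of the mitochondrial inner membrane, 2.25-fold, and Pnpt1, a mitochondrial RNA-processing enzyme, 2.24-fold. Krcc1 was 3.26-fold higher, Cul4b, the scaffold of a ubiquitin ligase, 2.89-fold, and Smim13 2.45-fold. Psmg4, a chaperone of proteasome assembly, was 2.17-fold higher, and Utp3, which acts in the making of the small ribosomal subunit, 2.13-fold. S1pr2, a receptor for sphingosine 1-phosphate, was 2.11-fold higher and Nsmce2, a SUMO ligase of DNA repair, 2.06-fold. Rps20, a ribosomal protein, was 2.25-fold higher, a value that is uncertain because ribosomal protein genes have many near-identical copies.

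Among the lower genes, Rps6kb1, the S6 kinase downstream of mTOR, had a signal 4.21-fold lower on the melatonin array. Tubb4a, a β-tubulin with close paralogs whose value is uncertain for that reason, was 4.23-fold lower. RT1-CE4, a class I gene of the rat major histocompatibility complex, also with near-identical relatives, was 3.86-fold lower, and Polm, a DNA polymerase of end joining, 3.62-fold. Pla2g4b, a cytosolic phospholipase, was 3.16-fold lower, Pkib, an inhibitor of protein kinase A, 2.98-fold, and Prodh2, an enzyme of hydroxyproline breakdown, 2.83-fold. Snph, which anchors mitochondria in axons, was 2.77-fold lower, Ripor2 2.77-fold, the olfactory receptor Or6al1 2.90-fold and Gabrq, a subunit of the GABA type A receptor, 2.74-fold. The Or6al1 probe was bright on the OS array (4.93 on the normalized log2 scale), unlike most olfactory receptor probes, so what it reads is uncertain.

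**Figure D1:**
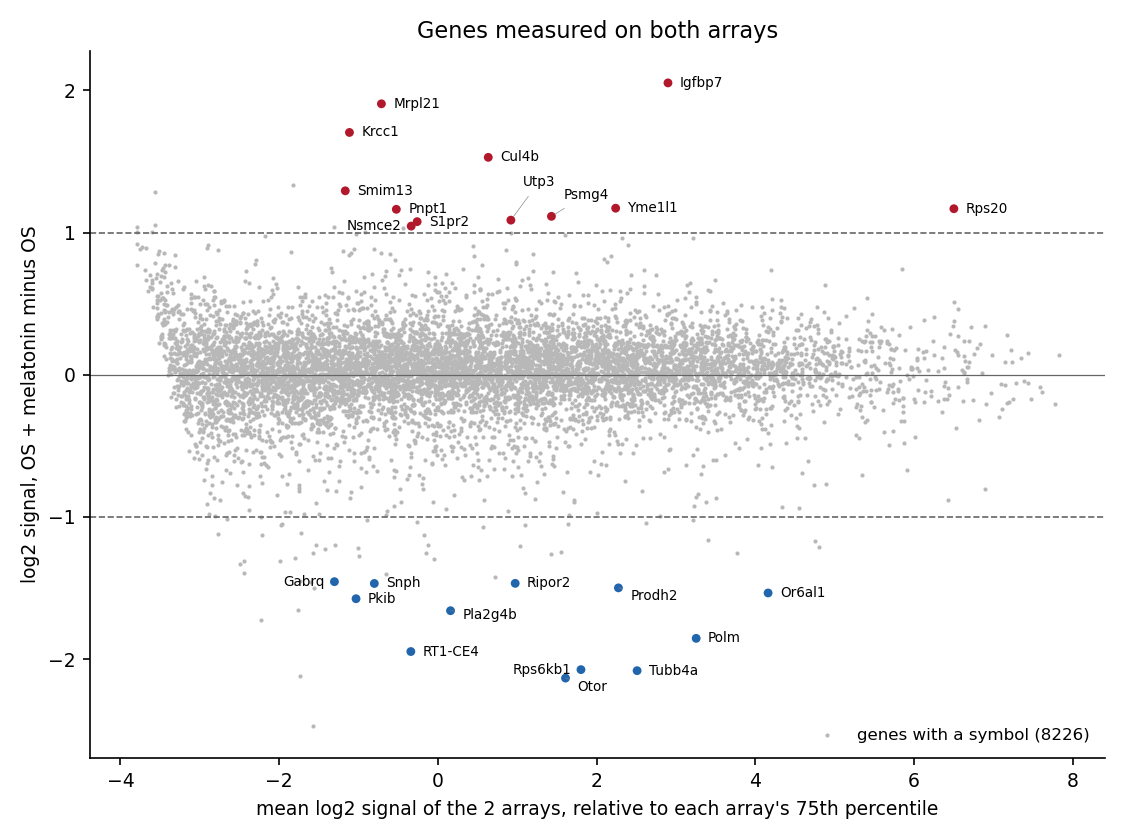
Each point is 1 of the 8226 genes with a symbol measured on both arrays; the horizontal axis is the mean log2 signal relative to each array's 75th percentile, the vertical axis the log2 signal with melatonin minus that without, and the dashed lines mark 2-fold. The 12 highest (red) and 12 lowest (blue) genes named by the fixed rule, all at or above the lower quartile of mean signal, are labelled, from Igfbp7 at 2.05 to Otor at -2.13, and 95.3% of genes lie within 1.5-fold.

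Each of these 24 genes was read by 1 spot, as were 74 of the 79 genes past 2-fold. Otor, Snph and Ripor2 each had another probe, not well above background on either array, with log2 ratios of 1.37, 0.92 and 0.0305. Another Pnpt1 probe was above background on the OS array only and gave -0.030. These probes did not bear out the ratios given above, though ratios at background say little. The array carries probes spotted 10 times, and for the 1033 of these with at least 8 usable spots the log2 ratio had a median SD of 0.159 between spots of a probe. The mean ratios of those probes had an SD of 0.149, against 0.307 for the 6349 genes read by 1 spot. Averaging over spots lowers the first value. From 1 random spot of each probe spotted 10 times the SD was 0.23, against 0.38 over all measured probes spotted once. The probes spotted 10 times were also brighter, at a mean log2 signal before scaling of 9.56 against 8.93. Across genes with several probes the ratios of 2 probes of a gene correlated at 0.15, and in 521 of 1124 such genes the probes differed in sign. The clearest value with repeated spots was that of Derl3, a gene of endoplasmic reticulum-associated degradation, which was 2.45-fold lower (log2 ratio -1.29, spot SD 0.19, 10 spots). It falls outside the naming rule and was chosen after its value was seen.

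Genes of odontoblasts and mineralization, the program that the induction medium is meant to start, lay in the middle of the profile as a group. Of 22 members on the array 15 were measured, none differed by 2-fold, and their median log2 ratio was 0.038, at the 45.3th percentile of 10000 random lists matched on expression. Higher values were those of Smpd3, a sphingomyelinase needed for skeletal mineralization (1.85-fold), and Postn, a matrix protein of periosteum and periodontal ligament (1.68-fold). Omd, osteomodulin, was 1.55-fold lower and Ankh, which carries pyrophosphate, 1.18-fold lower. Alkaline phosphatase (Alpl) had nearly equal signals, 3.52 and 3.53 on the normalized log2 scale, and the ratio of Nes was 1.00. Col1a1 was 1.21-fold and Enpp1 1.21-fold higher, Dcn 1.16-fold and Bgn 1.03-fold, while Ibsp and Sparc were each 1.13-fold lower. The log2 ratio of Spp1 was 0.13 and that of Col1a2 -0.13. Dspp and Dmp1, which encode the main non-collagenous dentin proteins, were not well above background on either array, nor were Phex and Phospho1. Bglap, Sp7 and Mepe were above it on the OS array only, with no fold that could be given.

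The melatonin receptor gene Mtnr1a had a low signal on both arrays and was 1.36-fold lower with melatonin. Tph1, tryptophan hydroxylase, was 1.32-fold lower, and Nqo2, an enzyme that binds melatonin, was 1.06-fold higher. These 3 were the measured members of the list of melatonin receptors and synthesis genes (median log2 ratio -0.40), too few for a percentile. The list median turned to 0.024 under normexp and to 0.54 over 7 genes with no filter on dim probes. It was -0.16 over 2 genes with the lower-quartile filter, so its direction is uncertain. Gpr50, Aanat, Asmt and Tph2 were not well above background on either array.

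The endoplasmic reticulum stress genes lay below the rest of the profile. Of 22 measured members 16 had a ratio below 0, with a median of -0.15, at the 0.06th percentile of random lists. Sdf2l1, a co-chaperone of the endoplasmic reticulum, was 1.78-fold lower by 2 probes (log2 ratios -0.87 and -0.79), and, chosen after their values were seen, the chaperone Hspa5 stood at -0.67, the pseudokinase Trib3 at -0.50 and the transcription factor Xbp1 at -0.45. Atf3, a stress-induced transcription factor, went the other way and was 1.63-fold higher. Glycolysis and hypoxia genes also lay low, with 18 of 23 measured members below 0 and a median of -0.12 (0.16th percentile). Car9, a hypoxia-induced carbonic anhydrase, was 1.29-fold lower, Hk1, a hexokinase, was 1.45-fold higher, and Ldha, lactate dehydrogenase A, and Vegfa, both chosen after their values were seen, stood at -0.33 and -0.34. Both lists stayed below the 2.5th percentile in all 9 alternative settings, and no member of either list differed by 2-fold.

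Notch signalling genes had a median of -0.16 over 8 measured members (2.13th percentile), which turned to 0.11 (31.0th) under normexp correction. The list also lay inside the range of random lists with quantile normalization (3.33th), no filter on dim probes (12.22th), the brightest probe of each gene (3.53th) and the authors' values (3.23th). Hey1, a Notch target, was 1.42-fold lower and the receptor Notch1 1.34-fold higher. Macrophage and osteoclast markers had a median of -0.19 over 10 measured members (0.93th percentile). Under normexp, where the median of all genes was 0.091, the macrophage median was 0.046 and the list lay at the 2.62th percentile, just inside the range of random lists. Lyz2, lysozyme of myeloid cells, was 5.54-fold lower by 1 spot, Laptm5, a lysosomal protein of blood cells, was 1.71-fold lower, and 3 of the 10 members had a ratio above 0. Of 32 lists with a percentile, these 4 lay outside the 95% range of random lists, all on the lower side. If the genes of a list varied independently, 1.6 lists would be expected there. Genes that move together would raise that number, so the 1.6 is no measure of chance between 2 cultures.

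**Figure D2:**
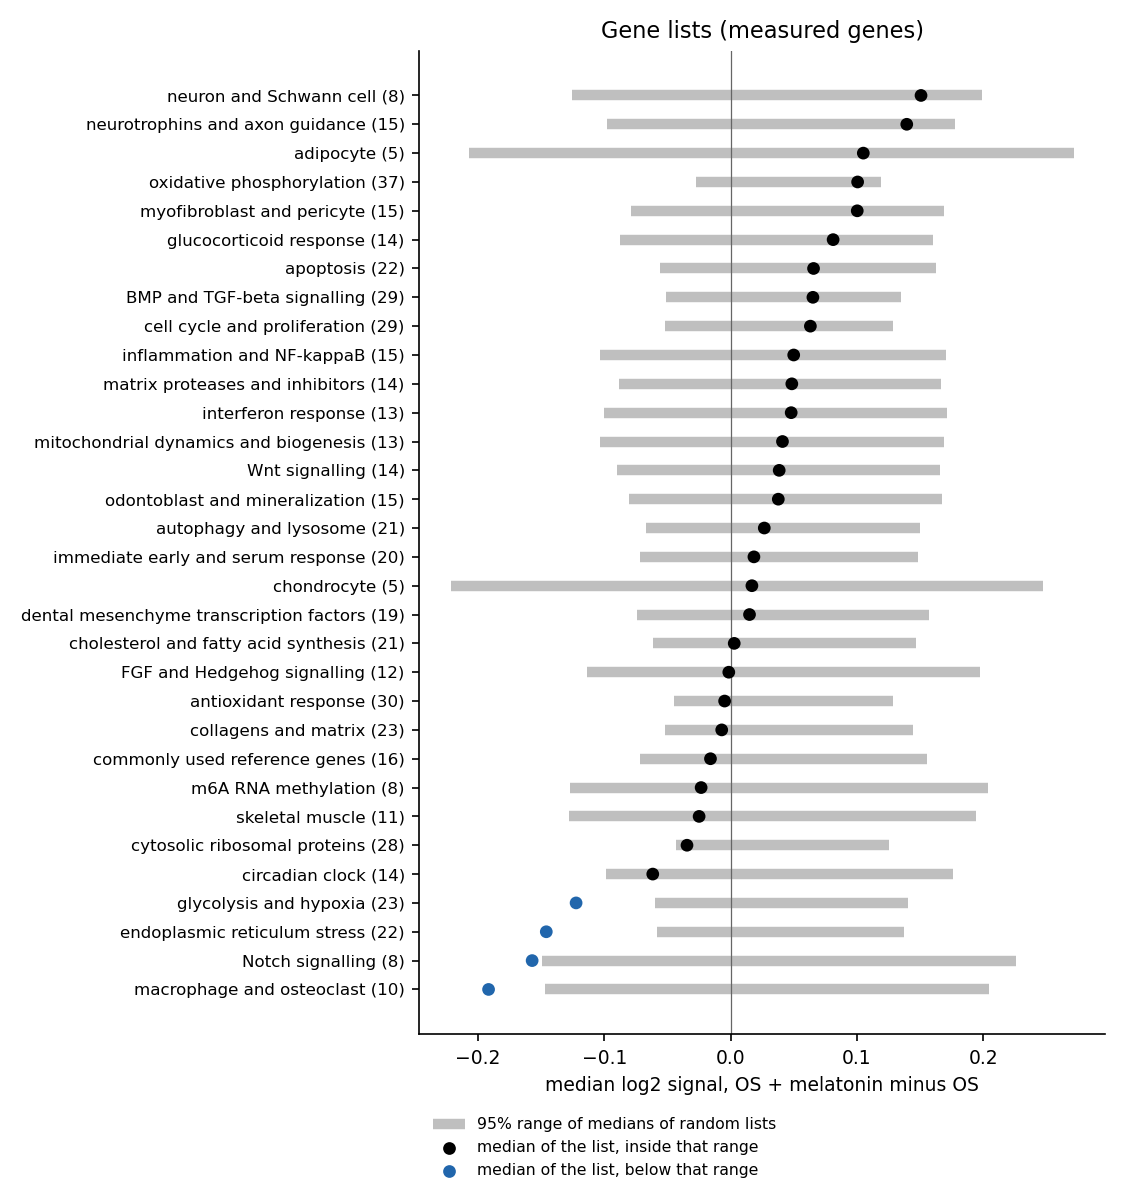
Dots give the median log2 signal with melatonin minus that without, over the measured members (number in brackets) of each of 32 gene lists, and grey bars the 95% range of medians of 10000 random lists matched on size and expression. The 4 lists in blue lie below their range, from -0.12 for glycolysis and hypoxia to -0.19 for macrophage and osteoclast, and under normexp correction the Notch median turns to 0.11 (31.0th percentile) and the macrophage median to 0.046 (2.62th). The Notch median lies inside its range under 4 further settings.

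The other 28 lists had medians between -0.062 and 0.15 and lay inside the range of random lists. Oxidative phosphorylation, the closest to the upper end among the large lists, had a median of 0.10 (92.5th percentile), with 27 of 37 members above 0. Ndufs7, a subunit of complex I, was 1.66-fold higher. Mitochondrial dynamics and biogenesis genes had a median of 0.041, with Pink1 1.28-fold and Tfam 1.24-fold higher. The antioxidant genes, often studied with melatonin, had a median of -0.0048, with Prdx1 1.35-fold higher and Prdx6 lower at a log2 ratio of -0.58. The circadian clock list had a median of -0.062 (7.29th percentile), with Per3 1.46-fold lower and Nr1d2 1.44-fold higher.

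Transcription factors of the dental mesenchyme had a median of 0.015, with Lhx6 1.46-fold higher and Nfic, which is needed for root odontoblasts, 1.45-fold lower. In the signalling lists the medians were 0.038 for Wnt (Frzb 1.49-fold higher, Sfrp4 1.23-fold lower), 0.065 for BMP and TGF-beta (Bmpr1a 1.42-fold higher, Tgfb2 1.45-fold lower) and -0.0015 for FGF and Hedgehog, where Fgf7 was 1.56-fold and Spry2 1.49-fold higher. Collagens and matrix had a median of -0.0071 (14.4th percentile), with Fmod 1.38-fold and Loxl1 1.32-fold higher, and matrix proteases and inhibitors 0.048, with Mmp19 1.24-fold and Adamts9 1.22-fold higher. Neurotrophin and axon guidance genes had a median of 0.14 (91.9th percentile), with the receptors Nrp2 1.81-fold and Robo1 1.37-fold higher.

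Cell cycle genes had a median of 0.063 over 29 members, with the kinesin Kif20a 1.75-fold and Cdca8 1.37-fold higher. Apoptosis genes had a median of 0.066, with Fas and Mcl1 each at a log2 ratio of 0.48, and autophagy and lysosome genes 0.027, with Atg12 1.58-fold and Gabarapl1 1.24-fold higher. Inflammation and NF-kappaB genes had a median of 0.050 (Ccl7 1.46-fold and Ptgs2 1.25-fold higher) and interferon response genes 0.048 (Ifi44 1.27-fold higher, Mx1 1.41-fold lower). Glucocorticoid response genes, relevant because both media held dexamethasone, had a median of 0.081, with Hsd11b1 1.32-fold higher and Fkbp5 1.29-fold lower. Immediate early genes had a median of 0.018, with Klf2 1.36-fold lower, and cholesterol and fatty acid synthesis 0.0028, with Fdft1 at a log2 ratio of 0.59 and Sc5d at 0.58. The m6A RNA methylation list had a median of -0.023, with Ythdf1 1.36-fold higher and Zc3h13, whose 3 probes disagreed in sign, 1.17-fold lower.

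Ribosomal protein genes had a median of -0.035, which turned to 0.001 under quantile normalization and 0.16 with the brightest probe of each gene, and Rpl11 was 1.43-fold and Rpl27 1.40-fold higher. Commonly used reference genes had a median of -0.016, but 2 of them stood lower with melatonin: Eef1a1, a translation elongation factor, by 1.85-fold and B2m, the light chain of class I major histocompatibility molecules, by 1.71-fold.

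**Figure D3:**
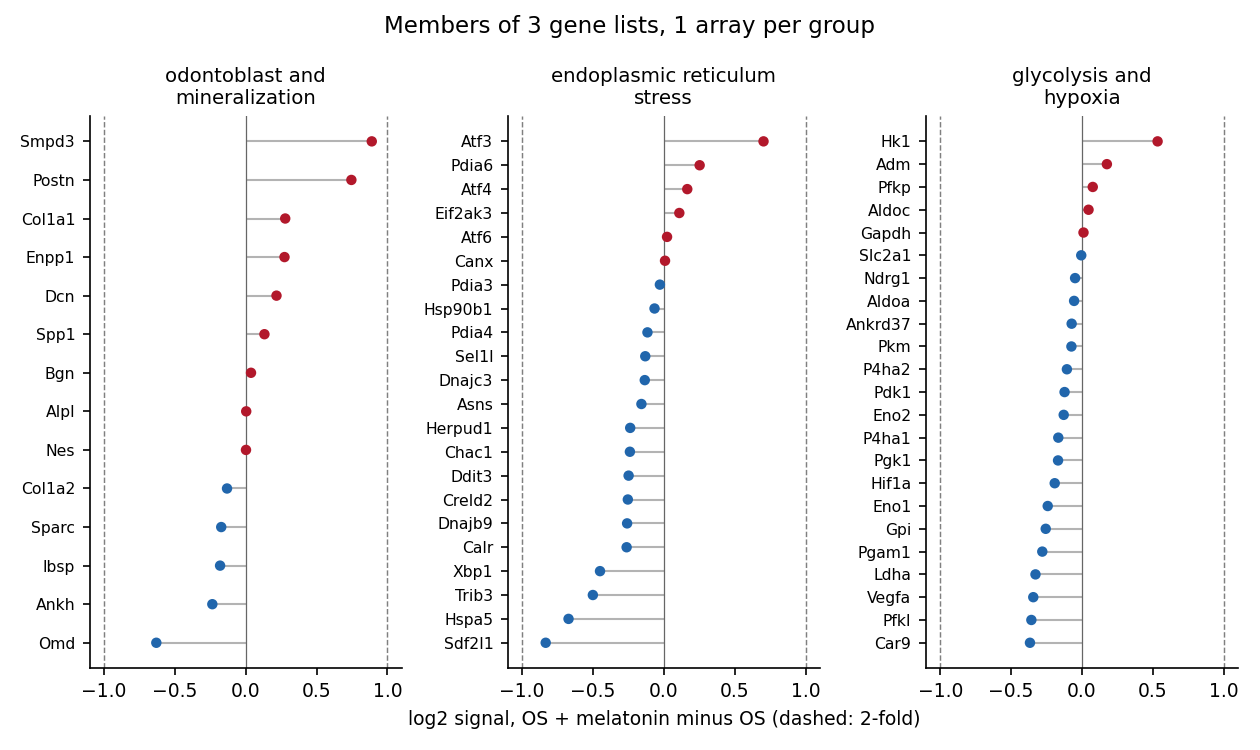
Each dot is 1 measured gene, with 1 odontoblast member not drawn, and the horizontal axis is its log2 signal with melatonin minus that without, with dashed lines at 2-fold. The odontoblast members lie on both sides of 0 (median 0.038), while 16 of 22 endoplasmic reticulum stress members and 18 of 23 glycolysis and hypoxia members lie below it.

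Markers of other cell types that a papilla culture could hold were mostly dim. Of the red cell and lymphocyte list 4 members were measured (median -0.29), with the β-globin gene Hbb 3.31-fold lower and its near-identical relatives making that value uncertain, and Cd3d 1.34-fold lower over 10 spots. The list median turned to 0.049 under normexp and to 0.94 over 13 members with no filter on dim probes. Endothelial markers had a median of -0.086 over 4 members, with Sox18 1.31-fold and Erg 1.06-fold lower. The endothelial median turned to 0.11 under normexp and to 0.20 over 14 members with no filter. Pecam1 and Kdr, chosen after their values were seen, were above background on the OS array only and at least 2.59-fold and 1.98-fold lower. Of the epithelium and ameloblast list only Tp63 was measured on both arrays (log2 ratio -0.029), and its 2 probes disagreed in sign. The list medians were -0.025 for skeletal muscle (Myh8 1.63-fold and Actc1 1.51-fold lower), 0.10 for myofibroblasts and pericytes (Lmod1 1.81-fold higher, Tpm2 1.43-fold lower) and 0.15 for neurons and Schwann cells (Pmp22 higher at 0.26, Sox10 lower at -0.29). Adipocyte markers had a median of 0.11, with Lpl 1.12-fold and Cd36 1.08-fold higher, and chondrocyte markers 0.017, with Hapln1 1.17-fold and Col2a1 1.14-fold higher. None of the lists in this group lay outside the range of random lists, and the lists with 4 or fewer measured members had no percentile.

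Some genes were well above background on 1 array only, and for these the ratio is a bound. Myh7, a myosin heavy chain of heart and slow muscle, was at least 5.01-fold lower with melatonin, Nrap, a muscle protein, at least 3.81-fold, Apobec2 at least 3.11-fold and Ankk1 at least 2.85-fold. Wdr89 was at least 7.57-fold higher, and the chemokine gene Cxcl9, the malic enzyme gene Me2 and the olfactory receptor Or2h1 were at least 2.43-fold, 2.43-fold and 2.38-fold higher. In all 975 genes were above background on the OS array alone and 20 on the melatonin array alone, but 744 of the 975 had a bound under 1 because the lowest signal called well above background was 20.7 on the OS array and 29.6 on the melatonin array. By this flag 14 and 16 genes had a bound of at least 2-fold. The floors differed after scaling, at -4.37 on the OS array and -3.47 on the melatonin array. This raises the bounds of genes on the melatonin array alone, of which 0 were under 1, so the 14 and 16 do not bear on direction. Cxcl9, Me2 and Or2h1 lay near the melatonin floor, at -3.08, -3.08 and -3.12. By the flag for a positive and significant signal, which reaches closer to background, 1057 genes were on the OS array alone and 858 on the melatonin array alone, and 95 and 797 had such a bound. Near background the negative control probe itself had a log2 ratio of 0.87 after scaling, so the bounds by this flag do not bear on direction.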

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

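All alternatives in this part were fixed before the data were examined except normexp, which was planned on the mean spot signal and run on the median after seeing the data. The 24 genes with the largest ratios among those at or above the lower quartile of mean signal kept their direction in all 9 settings, and at 2-fold 17 of them remained under normexp, 20 without a filter on dim probes, 23 with flagged spots kept or with the authors' values, and 24 in the others. Of all 108 named genes, 45 moved under normexp by at least the median SD between spots (0.159), 42 of them to a smaller ratio and 7 with a change of sign, and 12 moved without the filter, 8 to a smaller ratio and 4 with a change of sign. No named gene at or past 2-fold changed sign in any of the 9 settings that gave it a value. The count of genes higher with melatonin (21) was 9 under normexp, 1859 with no filter, 167 at 1.5-fold and 3 at 3-fold. The count of lower genes (58) was 35 under normexp, 229 with no filter, 37 with the lower-quartile filter (fewer genes tested, 6169), 217 at 1.5-fold and 10 at 3-fold. Without the filter the median of all genes moved to 0.16 from 0.039, and the negative control probe, at background, stood at 0.87, so these counts do not bear on direction among measured genes (20 of the 1859 and 48 of the 229 were called with the filter); the cause of the other shifts was not tested. Normexp turned the Notch median from -0.16 to 0.11 (0.1059, 31.0th percentile) and the macrophage and osteoclast median from -0.19 to 0.046 (2.62th percentile, from the 0.93th), while the median of all genes went to 0.091. Lists too small for a percentile moved too. Normexp turned the melatonin list from -0.40 to 0.024, endothelium from -0.086 to 0.11, and lymphocytes and red cells from -0.29 to 0.049. With no filter these lists stood at 0.54, 0.20 and 0.94, and epithelium went from -0.029 to 0.71. The lower-quartile filter put the melatonin list at -0.16, and the brightest probe put epithelium at 0.45. The Notch list was inside the random range at -0.12 (-0.1199) under quantile normalization, -0.012 with no filter, -0.14 (-0.1355) with the brightest probe and -0.12 (-0.1218) with the authors' values. The brightest probe put oxidative phosphorylation at 0.12 (98.0th percentile) and ribosomal proteins at 0.16 (99.6th), and no filter put ribosomal proteins at the 1.93th. Under the positive-and-significant flag 858 genes were on the melatonin array alone, against 20, and the bounds of at least 2-fold were 95 on the OS array and 797 on the melatonin array, against 14 and 16. That flag reaches closer to background, where the negative control probe stood at 0.87, so its bounds do not bear on direction either. Signal near background limits the dim genes. Scaling on spike-in controls was not run, since no spike-in probe was well above background on both arrays (1 was so in 10 of 10 spots on the OS array alone). No paired analysis was possible because each group had 1 array and no test was made, and no array could be left out.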

Other observations

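Tests chosen only after the result was seen, in this part, are those on spot noise, on dim probes and on the collagen list, the markers of heart, brain and liver measured on both arrays, the second endoplasmic reticulum, glycolysis and class I lists, and the genes named by repeated spots, with Casq2 and Tnnc1. The macrophage test was set before its result, left out once that was seen, and then reported as first set.

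Several heart muscle genes stood lower with melatonin beyond those named above, but Casq2 at 0.056 and Tnnc1 at -0.0013 did not, and the skeletal muscle list lay inside the range of random lists (median -0.025, 20.4th percentile). Probes with repeated spots gave Tnni3, cardiac troponin I, at a log2 ratio of -1.20 (spot SD 0.59, 9 spots), Nppb at -0.88 (SD 0.79) and Nppa, the atrial natriuretic peptide gene, at -0.83 (SD 1.06), so the spots of the natriuretic peptide probes disagreed widely. Among heart muscle markers not looked at before, Ckmt2, mitochondrial creatine kinase of muscle, was 2.75-fold lower, Myl3 2.48-fold, Csrp3 2.00-fold and Myh6 1.95-fold, while Ryr2 stood at 0.11 and Pln at -0.19. Gja5, a gap junction gene listed with them and already seen, was higher at 0.88.

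A second list of glycolysis and hypoxia genes had a median of -0.099 over 23 measured genes (0.32th percentile), but its members went both ways, 12 below 0 and 11 above, with the lactate exporter gene Slc16a3 at -0.96, Tpi1, triosephosphate isomerase, at -0.29 and Slc16a1, another lactate transporter gene, at 0.20. Class I presentation genes, looked at because of RT1-CE4 and B2m, had a median of -0.052 over 17 genes (5.51th percentile), inside the range of random lists, with RT1-S3 at -0.60 and Psmb10 at 0.64. Among probes with repeated spots, Atp6v1e1, a subunit of the vacuolar proton pump, stood at 0.68 and the apoptosis gene Bax at 0.42, against Hcrt at -0.70 and Slc2a4, the insulin-responsive glucose transporter gene, at -0.53.

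More features were at least 2-fold lower (219) than higher (110) with melatonin when unnamed features are counted. The excess was uneven between classes of features. The 1650 measured features with a probe ID only and no transcript accession gave 104 lower and 38 higher, and genes with a symbol 58 and 21. Ensembl transcript features gave 28 lower and 27 higher, and RefSeq XM features without a symbol 19 and 19. Why the classes differ was not tested. Measured spots around the lower ones had a median log2 ratio of -0.027 (95% bootstrap interval -0.055 to -0.0065), which argues against an artefact that covers neighbouring spots. A defect of 1 spot would not show in this test. Olfactory receptor probes, which read little RNA in most tissues, had a signal over the negative controls equal to 2.53% (2.36 to 2.72) of the median signal lost. For probes that read genomic DNA no more strongly than those do, this argues against such DNA in the OS sample. Whether the features with a probe ID only are such probes was not tested. The lower features had a median signal rank at the 44.5th percentile (37.4 to 49.9), so the dimmest measured probes did not make up most of them. The higher features had a median rank of 37.2. Of the 58 lower genes with a symbol 37 stayed with the lower-quartile filter, so noise of dim probes was not excluded for a part of them. Spot noise was not excluded: 1 random spot of each probe spotted 10 times put 0.342% (0.0915 to 0.551) of probes past 2-fold, against 2.65% of probes spotted once, but among probes with a symbol, which are more common in the first class, the shares were 0.378% (0.110 to 0.661) and 1.1%. A difference between the 2 samples, by melatonin or by chance, stays open too and cannot be separated with 1 array each, and whether each sample is 1 culture or a pool is not known here.

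The low endoplasmic reticulum stress list stayed at the 0.04th percentile after loess correction. The random lists were already matched on mean signal, so this percentile could hardly have changed and decides nothing about a trend with signal. The list's median, which the correction could have removed, was -0.18 after it and -0.15 before, which argues against such a trend. The collagens and matrix list, the main secreted cargo, lay at the 14.44th percentile, against a general loss of secretory transcripts. A second list of 52 measured folding, export and degradation genes lay at the 96.7th percentile with a median of 0.10. For those genes this goes against a lower folding program as a whole. The second list held only genes not looked at before, so the degradation gene Derl3 (-1.29) was not in it. An effect of melatonin on part of the first list and a chance difference in the state of the 2 samples stay open and were not tested, and Atf3, a stress-induced member, was 1.63-fold higher.

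The lower heart muscle genes could come from more heart muscle RNA in the sample without melatonin. The lower macrophage genes could come from fewer macrophages in the sample with it. The heart list was prompted by Tnni3, Nppa, Nppb, Myh7, Nrap and Apobec2 in these same data; over its 21 unseen markers (of 32 on the array) well above background on the OS array the median was -0.35 (-0.75 to -0.071), between the -0.5 set for that source and the -0.2 set against it, so the test left it open; it counted dim genes at their bounds. Restricted after that to the 15 markers measured on both arrays, the median was -0.63, with 14 below 0 and no random list as low, though Pln and Ryr2, the brightest, stood at -0.19 and 0.11. Brain markers (median 0.11, -0.15 to 0.26) and liver markers (0.085, -0.19 to 0.73) left RNA of several other tissues in the OS sample open, since 5 of 10 and 3 of 6 values were limits, or held one, set by the floor of the melatonin array, and the 6 brain and 3 liver markers with a probe measured on both arrays (Mobp among them, which also had a probe at its limit and is counted in both numbers; medians 0.0445, -0.23 to 0.31, and -0.022, -0.36 to 0.12) were too few to decide. On the OS array itself 24 of 30 liver markers, Alb, Apoa1 and Ttr among them, and 12 of 22 brain markers were not well above background, which goes against a large share of such RNA but sets no limit on a small one. Of the 5 brighter macrophage markers 1, Acp5 at 0.14, was not lower, which left fewer macrophages neither excluded nor borne out.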
